A study of Caenorhabditis elegans with 2 samples.

How the data were processed

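Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was carried out against eGFP-tagged CEH-28 in whole Caenorhabditis elegans at the last larval stage (L4), per the labels. There were 2 biological replicates of 1 group, recorded as separate biosamples, and both replicates were tied to the same control per the deposited lineage notes. The labels give no extraction protocol. The aligner, the peak caller and their versions are not given in the sources used here.

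Peaks were deposited as called for each replicate and for both replicates pooled, as relaxed lists of peaks and background, and as a list thresholded by the irreproducible discovery rate (IDR). Each list was deposited on the ce10 and the ce11 genome builds, which made 8 lists. The height of each peak is a signal value given by the authors, with no stated scale. It was used to describe, rank and filter peaks within a list, to set the replicates side by side across peaks and to compare the builds at equal rank. The deposited lists also hold −log10 q values, which reached a maximum of 3.76 at all 1739 summits of the ce11 thresholded list and so could not rank them. The p-value field was left unset in all lists. The number of reads behind each list is unknown, because the lists hold no counts, so no value below carries a depth-based interval.

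Coordinates are on ce11, the same assembly as WBcel235, with genes from Ensembl release 115. The ce10 lists served for counts, chromosome shares, replicate overlap and correlation among themselves, and for signals at equal rank beside ce11. A list entry is a summit, and a region can hold several. The thresholded list held 1739 summits in 1660 regions, and these summits were exactly the 1739 summits of the pooled list with the highest signal. In 1 case the summit offset lay outside its region.

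Replicates were compared through the regions of the 1739 summits with the highest signal in each, called its highest regions below. A region with several such summits counts once for each. The share of those of replicate 1 that overlapped one of replicate 2 by at least 1 bp was taken. Chance was estimated from 1000 circular shifts along each chromosome (one-sided permutation test). Promoter windows reached from 1000 bp upstream to 500 bp downstream of each protein-coding gene start. Chromosome shares were tested against length with an exact binomial test (two-sided). Members of 16 gene lists with a summit in the promoter window were compared with all other protein-coding genes by Fisher's exact test (two-sided) with Benjamini-Hochberg adjustment over the lists, and 5 non-coding classes with circular shifts. A site of NK-2 class homeodomain proteins, TYAAGTG, was sought within 100 bp of summits and in the window 1000 bp to the right (exact McNemar test, two-sided). All 6-mers were compared between summit windows and windows 1000 bp to either side (Fisher's exact test, Benjamini-Hochberg). Intervals on shares of summits are 95% Wilson intervals and those on shares of genes are exact binomial. Both cover counting error only and take summits or genes as independent, as do the binomial, McNemar and Fisher's exact tests. For a gene list with a count of 0, the share that 3 counts would make is given as its limit.

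The gene lists, the main tests, most alternatives and the rule for named genes were fixed before the data were examined. The rule named the gene with the start nearest to each of the 15 summits with the highest signal, every gene of a list for the M4 neuron and CEH-28, up to 3 members of each other list with the highest peaks, and ceh-28 and unc-119. Outside the rule, egl-21 and genes in which one of the 15 summits lay were named after the values were seen. Of the 8 symbols of the M4 list, eya-2 was not matched to the annotation. Annotation classes, chromosomes other than X, single 6-mers in subsets of peaks or by rank of signal and the counts of sites per peak were examined without having been fixed in advance. The alternatives added later are named with their values.

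The tests were checked on simulated data. A planted replicate overlap of 70 percent came back as 68.3, and lists with a planted log2 odds ratio of 4.00 gave a mean of 3.99 over 100 draws. The planted lists were larger than most lists used here, and the planted effect was stronger than that of the ribosomal protein genes. The power of the tests on small lists was thus not checked. With nothing planted, at random positions of the genome, 0 of 2080 6-mers were called. Real summits can lie close together, so this sets no error rate for them. Alternatives covered other overlap rules, promoter windows, thresholds, controls, the ce10 lists and each replicate alone. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used.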

Results

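CEH-28 is a homeodomain protein of the NK-2 class known for its role in the M4 neuron of the worm pharynx. ChIP-seq was carried out against the eGFP-tagged protein in whole mixed-sex L4 larvae of strain OP241. The strain carries a tagged ceh-28 transgene and an unc-119 rescue gene. All cells of the larvae were sampled together, so signal from the M4 neuron was not separated from that of other cells. The group had 2 replicates. On ce11, 23410 summits were called in replicate 1, 26414 in replicate 2 and 20803 in the pooled replicates, and 1739 summits in 1660 regions passed the IDR threshold. The thresholded regions had a median width of 384 bp and covered 0.598% of the genome. With no other condition in the series, the comparisons set replicates against each other, peaks against chance placement and peaks against weaker regions.

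Most regions that stood highest in replicate 1 also stood highest in replicate 2. The summit with the highest pooled signal, in an intron of Y22D7AL.7, had signal values of 1728 in replicate 1 and 604 in replicate 2 and was the highest in each list. Of the 1739 summits with the highest signal in replicate 1, 72.6% (95% Wilson interval 70.4 to 74.6) had a region that overlapped one of replicate 2. The mean under circular shifts was 1.49%, and the permutation p of 0.000999 was the smallest the shifts could give. With 1 summit per region, an alternative added later, the share was 70.6%. Shifts stand for random placement, so agreement that came from the control both replicates shared was not separated in the overlap or the correlation below. The thresholded list drew more on replicate 1, since 92.4% of its summits lay in the highest regions of replicate 1 and 78.2% in those of replicate 2. Across 1733 thresholded summits with a region in both lists, the signals had a Spearman correlation of 0.736 and a Pearson correlation of 0.829 on the log10 scale, across peaks, which are not independent replicates. Signals were higher in replicate 1 at 99.5% of them, with a median ratio of 2.76, on a scale that is not stated.

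**Figure D1:**
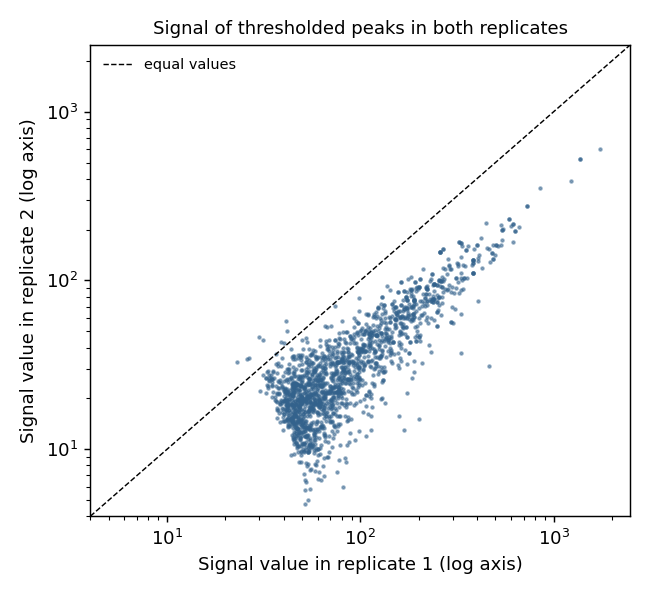
Signal values of thresholded peaks in replicate 1 (x axis, log scale, authors' units) and replicate 2 (y axis, log scale), 1 point per summit found in both lists; the dashed line marks equal values. Across the 1733 points the Spearman correlation is 0.736.

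The highest peaks lay in introns, in 3' UTRs or between genes, mostly away from gene starts. The first was on chromosome III at 1580159 to 1580683, 3586 bp downstream of the start of Y22D7AL.7, with a signal of 2314 and 9 ATCGAT sites. The second lay in an intron of mac-1 (chromosome II, 13315832 to 13316798, signal 1878) and held 24 ATCGAT sites. The third had egrh-2 as its nearest start but lay in a 3' UTR of the plexin gene plx-1 (chromosome IV, 983477 to 984099, signal 1613). The fourth was between genes on X at 8036104 to 8036684, 4885 bp upstream of xol-1, the switch gene of sex determination, with a signal of 1193. The next were nearest to nlp-69 (signal 976, in a 3' UTR of sec-23), W02H3.3 (865), Y48G9A.7 (832), ugt-31 (828), H14E04.3 (825), C55C3.3 (821) and Y48E1C.1 (777). The last of the 15 were nearest to Y55F3AM.5 (756), Y66A7A.4 (751), Y38F2AR.10 (749) and F55G7.5 (714). Only C55C3.3, Y48E1C.1 and Y55F3AM.5 had a start within 1000 bp of these 15 summits.

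Summits favoured promoter windows and introns and avoided coding exons. Of the 1739 thresholded summits, 38.0% (interval 35.7 to 40.3) lay in a promoter window, against 25.7% under circular shifts (one-sided permutation p = 0.000999, the smallest possible). The share was 37.6% among the highest regions of replicate 1 and 38.4% among those of replicate 2. Weaker pooled regions outside the thresholded list also lay there in 34.3% of cases, an odds ratio of 1.17 (Fisher's exact p = 0.00244), but the direction turned for the peaks at or above the median signal, at 30.1% (Fisher's exact p = 0.0105). Introns held 44.1% of summits against 35.2% under shifts, and coding exons 7.82% against 25.0% (adjusted p = 0.00300 for each, two-sided permutation test). The 3' UTRs held 7.07% against 3.42% and the 5' UTRs 3.16% against 1.40%, with the same adjusted p. Between genes lay 37.6% against 34.9%, which did not pass (adjusted permutation p = 0.0743).

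Chromosomes I and III carried the most peaks per length and X and V the fewest. Chromosome I held 476 summits, 31.6 per Mb, and chromosome III held 396, 28.7 per Mb, against 14.1 on II, 15.2 on IV, 9.13 on V. X held 195 summits, 11.2% of them (interval 9.82 to 12.8) and 17.7% of the length (exact binomial p = 1.2e-13), and its share of weaker pooled regions was 17.1% (odds ratio 0.613, Fisher's exact p = 5.52e-11). On the autosomes, 82.9% of summits (interval 80.9 to 84.7) lay in the outer 2 of 3 equal parts, against 66.7% of the length (exact binomial p = 1.76e-46), while the weaker regions lay there in 63.6% of cases. Per 1000 genomic ATCGAT sites, counting summits with or without the site, X held 51.5. The values were 63.9 on I, 58.5 on III, 40.6 on IV, 37.0 on II and 26.9 on V. Only 47.2% of X summits had ATCGAT, against 79.7% on the autosomes. The number of sites was thus not shown to account for the low count on X. In the replicates alone, X held 11.3% and 11.7%, and the outer parts 82.8% and 80.0%. With 1 summit per region, an alternative added later, X held 11.7% and the outer parts 82.1%. The tests and intervals here took summits as independent, but summits can lie close together, and so can regions. Their p-values can thus be too small and their intervals too narrow.

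Of the fixed gene lists, ribosomal protein genes carried peaks more often than other genes and chemoreceptor genes less often. Promoter windows of 768 of 19973 protein-coding genes held a summit, 3.85%. Among ribosomal protein genes 15 of 80 did (18.8%, interval 10.9 to 29.0, adjusted p = 2.68e-06 by Fisher's exact test), led by rpl-3 (chromosome III, 3867455 to 3867697, signal 281), rpl-23 (200) and rpl-15 (176), all upstream of the gene start. The 15 peaks were in 15 separate regions. Chemoreceptor genes had 6 of 1171 (0.512%, Fisher's exact adjusted p = 2.39e-12), with sre-50 (402), sre-26 (108) and srj-26 (74.6) highest. Neither test matched genes by chromosome, although summits per Mb ranged from 9.13 on V to 31.6 on I. Chromosome was thus not separated from gene class. Both calls were closer to the threshold when only genes with any pooled summit in the window were compared, thresholded ones included, with ribosomal protein genes at 23.1% and others at 11.2%, chemoreceptors at 4.08% and others at 11.4%, and adjusted p of 0.0427 for each.

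Genes of the M4 neuron and CEH-28 had no thresholded peak in their promoter windows. In whole larvae, this does not show that binding was absent in the M4 neuron. Of the 7 matched genes, 0 had a summit in the promoter window, which allows a share of up to 42.9% by the rule of 3 counts (exact 95% upper bound 41.0%). The ligand gene dbl-1, known as a target of CEH-28, had its nearest thresholded summit 101215 bp away, and its only weaker region in the window had a signal of 13.6 at rank 18455 of the pooled list. The FGF gene egl-17 had a weaker region at rank 4888 (signal 29.2, nearest thresholded summit 79477 bp away). The serotonin receptor gene ser-7 had a thresholded summit 5579 bp from its start, and for zag-1, ceh-32 and ceh-34 the nearest lay 113266, 259768 and 261156 bp away. At ceh-28 itself the nearest lay 70700 bp away.

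Synaptic and panneuronal genes had peaks in 4 of 28 cases (14.3%, Fisher's exact adjusted p = 0.114): snb-1, which encodes synaptobrevin (signal 159), unc-18 (148), syd-2 (109) and egl-21, the last named after its value was seen. This list passed the threshold with 500 bp either side of the start (14.3%, Fisher's exact adjusted p = 0.0458), with the nearest start up to 2000 bp away (32.1%, 1.81e-05), in the peaks at or above the median signal (10.7%, 0.0440) and in replicate 1 alone (21.4%, 0.00310). It did not in replicate 2 alone (14.3%, Fisher's exact adjusted p = 0.111) or among genes with any pooled summit in the window (23.5%, 0.374). DBL-1 signalling genes had 2 of 12, the Smad genes sma-3 (77.4) and sma-4 (74.4), with Fisher's exact adjusted p = 0.173, and 8.33% in replicate 2 alone against 16.7% with both. Heat shock genes had 3 of 22, hsp-60 (70.9), hsp-1 (64.5) and hsp-3 (57.1), with Fisher's exact adjusted p = 0.143, and 4.55% in replicate 2 alone against 13.6% with both. Nuclear hormone receptor genes had 6 of 269 (nhr-92 at 274, nhr-49 at 248 and nhr-48 at 102, Fisher's exact adjusted p = 0.401), and cuticle collagens 3 of 173 (col-104 at 221, col-97 at 190 and col-132 at 57.1, adjusted p = 0.404). Neuropeptide genes had 1 of 140 (ins-39 at 250, Fisher's exact adjusted p = 0.143) and histones 1 of 72 (his-37 at 101, adjusted p = 0.848). No member had a peak among 95 homeobox genes (Fisher's exact adjusted p = 0.143), 33 body wall muscle and 29 germline genes (0.851 for each), 22 intestine, 16 pharyngeal and 7 cholinergic genes (1 for each). By the rule of 3 counts the limits are 3.16, 9.09, 10.3, 13.6, 18.8 and 42.9%, in the same order. The exact 95% upper bounds are 3.81, 10.6, 11.9, 15.4, 20.6 and 41.0%.

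**Figure D2:**
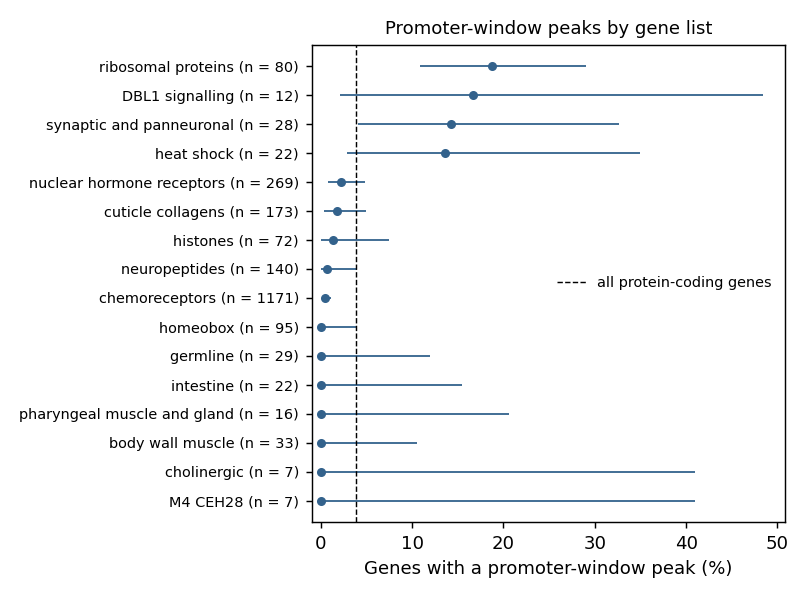
Share of genes in each list with a thresholded summit in the promoter window (x axis, percent), with exact 95% binomial intervals as bars and n the number of genes; the dashed line is the share of all protein-coding genes, 3.85%. Ribosomal protein genes lie at 18.8% and chemoreceptors at 0.512%.

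More small nucleolar RNA genes carried peaks than under shifts of the summits. Shifts stand for random placement, and the non-coding classes were not compared with other genes. A general preference of summits for gene starts was thus not separated. Windows of 29 of 346 snoRNA genes held a summit, against a mean of 8.56 genes (adjusted p = 0.00999, two-sided permutation test), led by M7.15 (signal 248), F01D5.12 (226) and T27A8.8 (199). The snoRNA peaks lay in 26 regions. Of these, 4 were also regions of ribosomal protein genes, and 7 of the 29 snoRNA genes shared them. Of 261 miRNA genes 15 had a summit, in 11 regions, against 5.70 (adjusted permutation p = 0.0350), led by mir-76 (272), mir-54 and mir-55, which shared 1 region (124). The miRNA count lost its call in replicate 1 alone, at 12 genes (permutation p = 0.0779), and in the peaks at or above the median signal, at 4 genes against 2.71 (permutation p = 0.547). The counts were 16 of 612 tRNA genes (adjusted permutation p = 0.632), 7 of 129 snRNA genes (0.133) and 0 of 20 rRNA genes (1). The highest among tRNA genes were WBGene00022939 (1193), which lay beside the X peak upstream of xol-1, WBGene00023188 (434) and WBGene00014147 (368). The highest among snRNA genes were Y54G9A.8 (608), sls-2.1 (85.9) and C47F8.9 (79.5).

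The NK-2 site was no more common at summits than beside them, whereas ATCGAT was found at most summits. TYAAGTG lay within 100 bp of 2.82% of summits (interval 2.14 to 3.71) and in 3.45% of windows to the right (exact McNemar p = 0.334). ATCGAT lay at 76.1% (interval 74.0 to 78.0), against 17.4% of windows on both sides, and had the lowest p of 2080 6-mers. It lay at 76.1% of the highest regions of replicate 1 and 67.3% of those of replicate 2. In all, 259 6-mers were more and 581 less common at summits (adjusted p under 0.05, Fisher's exact test), and TATCGA (68.5% against 18.6%), CGATAA (57.8% against 16.8%), AGAGAG (20.9% against 7.73%) and CGTCTC (16.6% against 5.61%) were among the former.

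**Figure D3:**
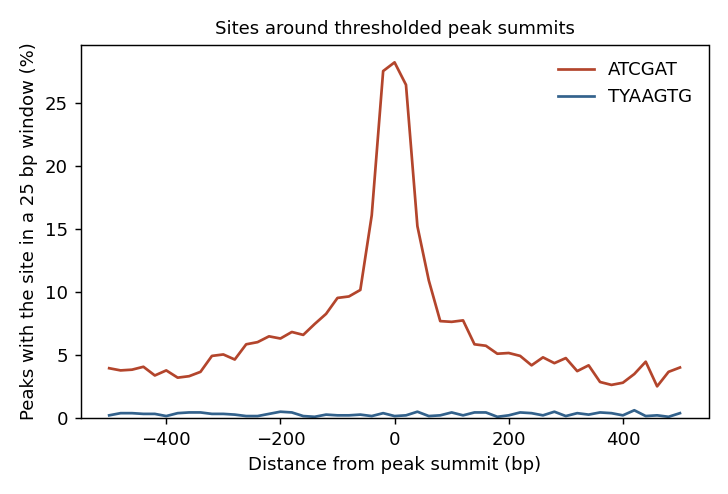
Share of thresholded peaks with ATCGAT or TYAAGTG in a 25 bp window (y axis, percent) by distance of the window from the summit (x axis, bp). ATCGAT reached 28.2% at the summit and TYAAGTG was at 0.173% there.

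Peaks with more ATCGAT sites had higher signals. The median signal was 77.8 at the 416 summits with 0 sites within 100 bp, 80.1 with 1 site, 89.3 with 2, 129 with 3 and 218 at the 200 summits with 4 or more (Spearman correlation 0.376 across 1739 summits, which are not independent replicates). In the pooled list, the share with ATCGAT fell from 76.1% among the first 1739 summits to 51.6% among the next 1739 and 14.3% among the last 1674. The share was 68.8% of summits in promoter windows and 80.5% of those outside (Fisher's exact p = 3.46e-08). In the windows to the right it was 12.3% and 20.9%. A high share beside the summits limits how large a ratio to it can be. Which of these places had the stronger excess was thus not settled. On X, 47.2% of summits had ATCGAT and on the autosomes 79.7%. The windows to the right had it in 3.08% (6 of 195 windows) and 19.5%, and those to the left in 5.64% and 18.7%. Both the summit share and the side shares were thus lower on X. Whether the excess at summits differed between X and the autosomes was not settled, for the same reason.

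**Figure D4:**
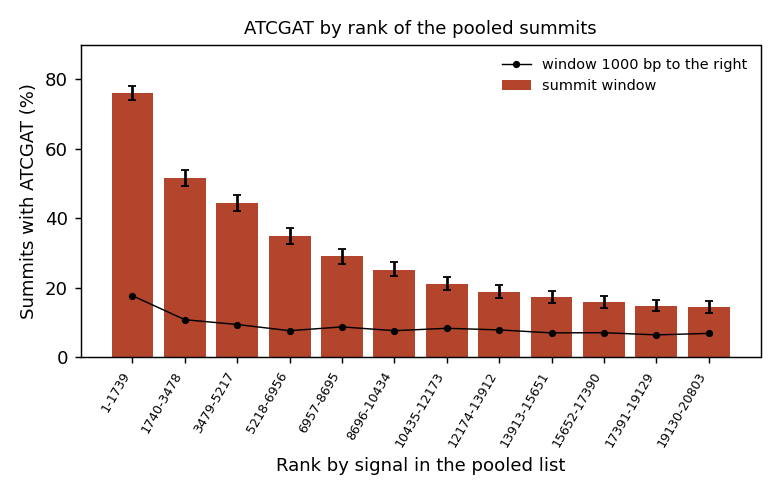
Share of pooled summits with ATCGAT within 100 bp (bars, percent, with 95% Wilson intervals) by rank of signal (x axis), and the share in windows 1000 bp to the right (black points). The share falls from 76.1% in the first bin to 14.3% in the last.

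Neither transgene locus stood out among weaker regions within 20 kb. Around ceh-28 (X, 13074673 to 13076092) there were 3 pooled summits, and 15.9% of other protein-coding genes had as many or fewer. Around unc-119 (chromosome III, 10902641 to 10908935) there were 9, with 66.6% of genes at or below. Within 50 kb unc-119 had 36, and 95.5% of genes had as many or fewer, past the threshold of 95%, while ceh-28 had 17 at 41.6%. Of the thresholded summits, 0 lay within 20 kb of either gene.

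Both builds gave similar counts and signals at equal rank, and positions were not matched between them. The thresholded list held 1739 summits on ce11 and 1741 on ce10, and the median difference in signal at equal rank was 0.493%. For the pooled list the counts were 20803 and 20695.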

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

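Of the alternatives, the summit-per-region choice, the replicate alternatives for 6-mers and all alternatives for introns, coding exons, snoRNA and miRNA genes, chromosomes I and III and promoters against weaker regions were chosen after seeing the data. Of 47 alternative values of the main results, 38 stayed the same. For values with a threshold this meant the same direction and side of it, and for counts within 1.5 times the main count. For the correlation it meant within its 95% bootstrap interval over peaks, 0.708 to 0.763. The gene lists past the threshold went from 2 to 3 in 4 of the alternative settings, each time because the synaptic list passed. The replicate signal correlation was 0.793 in the peaks at or above the median signal and 0.680 with summits matched within 100 bp. TYAAGTG turned to slightly more common at summits within 50 bp (1.44% against 1.32%, exact McNemar p = 0.885). It was less common past the threshold for the core AAGTG (29.4% against 33.5%, exact McNemar p = 0.00920), for TNAAGTG (6.56% against 8.40%, p = 0.0416) and against weaker regions (2.82% against 4.40%, p = 0.00123). With 1 replicate left out its share ranged from 2.30 to 2.88%, past the threshold in replicate 2 alone (exact McNemar p = 0.00322). The number of 6-mers more common at summits was 124 in the peaks at or above the median signal, of which 118 were also called with all peaks; fewer peaks were tested there. The unc-119 locus rose to 95.5% of genes within 50 kb. Among lists without a call, pharyngeal genes moved above other genes at 6.25% with the nearest start within 2000 bp, and DBL-1 signalling and heat shock genes to 0% in the peaks at or above the median signal. The promoter share fell below that of weaker regions in the peaks at or above the median signal (30.1% against 34.3%) and with the nearest start within 2000 bp (60.9% against 61.5%, Fisher's exact p = 0.643). Except where a construction is named, the cause was not tested. No paired analysis was possible because the series has 1 group. The read depth is unknown, so what depth limits cannot be given.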

Other observations

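The tests of base composition, tandem copies, a different tagged protein, the number of weaker regions on chromosomes I and III, ATCGAT at ribosomal protein genes, AGAGAC and the X sequence were chosen only after the result was seen. ATCGAT lay at 4 of 15 summits of ribosomal protein genes (26.7%) and at 69.8% of the 645 other summits in promoter windows (Fisher's exact p = 0.000857). AGAGAC lay at 21.8% of summits in promoter windows and 14.6% of those outside (Fisher's exact p = 0.000152). With no other group in the series, no biological explanation was tested for any pattern below.

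ATCGAT, not the NK-2 site, marked the thresholded summits. Repeats were argued against as the whole cause, since 56.0% of the 134 summit windows with no soft-masked base had ATCGAT. Such side windows had it in 9.52%, although the unmasked windows are 7.71% of summits. Exact tandem copies within 100 bp were argued against as the whole cause, since 37.2% of summits had exactly 1 site against 11.3% of side windows. Imperfect copies and copies farther away were not counted, so arrays of those stay open. Other 6-mers of the same composition had a median summit-to-side ratio of 0.736, 80.5% of peaks outside promoter windows had ATCGAT, and the lower replicate had 67.3%, which count against base composition, open promoters and a single replicate. That a protein other than the labelled one was precipitated cannot be told apart from CEH-28 reaching such sites, because TYAAGTG at 2.82% of summits decides neither and the lists hold no protein identity. Regions that come up in ChIP of many proteins stay open as well, untested because no other ChIP lists were used here.

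Chromosomes I and III held 2.49 times as many summits per Mb as the others (interval 2.27 to 2.73). They were grouped because they held the most summits per Mb in these data, so part of each ratio can follow from that choice. The intervals do not allow for it and take summits as independent. Per genomic ATCGAT site, counting summits with or without the site, the ratio fell to 1.64. Its lower 95% bound was above the limit set before this ratio was seen. Scaling by the total number of single sites thus left part of the excess. Sites close together, where signals were higher, were not counted apart, so their placement stays open. Scaling by the number of pooled summits also left part of the excess, with a ratio per pooled summit of 1.81 (interval 1.65 to 1.99). What else differs between these chromosomes was not tested.

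If extra transgene copies raised the number of called regions around their genes, that number would stand out there. Within 20 kb, 15.9% of other genes had as many pooled summits as ceh-28 or fewer, and 66.6% as many as unc-119 or fewer, both under the 95% set beforehand. This does not exclude extra copies, since the strain of the control is not given in the sources used here and a control with the same copies would cancel them. At 50 kb unc-119 reached 95.5%, so a raised count farther from that gene stays open.

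A sequence noticed while reading the 15 highest peaks, GCGCAGGG, lay at 14 of 195 X summits and 1 of 1544 autosomal summits. With those 15 peaks left out it lay at 12 of 192 X summits (6.25%, Wilson interval 3.61 to 10.6) and 1 of 1532 autosomal summits (Fisher's exact p = 3.13e-11). It resembles the motif of sites that recruit the X chromosome dosage compensation complex, and whether the peaks lie at such sites was not tested.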
